A study of Mus musculus with 9 samples.

How the data were processed

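Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in E14Tg2A cells, a mouse embryonic stem cell line grown without feeder cells in serum and leukemia inhibitory factor. The series holds 9 samples in 8 groups: Phf19 (2 replicates), Suz12, H3K27me3 in cells with a random control short hairpin RNA (shRd), H3K27me3 in cells depleted of Phf19 with a hairpin against it (shPhf19), H3K36me3, H3K36me2 and 2 IgG controls, 1 of them for the Phf19 experiment. Per the labels' protocols, cells were crosslinked with formaldehyde, sonicated, and libraries were made with a commercial kit.

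The deposited values are 4 lists of genomic sites, each giving the chromosome, start and end of a site and no score, height, fold or p-value. Bowtie 0.12.7, MACS 1.4.1 and the mouse build mm9 are named in the submitters' processing notes, without their roles. Per the series' design text, the Phf19 list holds the sites found in both replicates. The Suz12 list and each H3K27me3 list rest on 1 library. The peak threshold, the control library used for each list and any later filter are not given in the sources used here. Every site lies inside the mm9 chromosome lengths and no list holds a duplicated site. Read depth is unknown because the lists hold no counts. Per the labels, the H3K27me3 antibodies of the shRd and shPhf19 libraries carry the catalogue numbers 07449 and 07450; whether the antibodies differed or a number was entered wrongly is not given in the sources used here. The H3K36me3, H3K36me2 and IgG samples have no list among the files used here and were not analysed here.

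Site width was taken as end minus start, and coordinates are printed as the lists give them; whether starts count from 0 or 1 is not given in the sources used here. Sites of 2 lists were called overlapping when they shared at least 1 base. Each share of sites carries an exact Clopper-Pearson 95% interval, which covers counting error only and treats sites as independent, although neighbouring sites are not. For the share expected without a relation, the sites of the first list were placed at random 1000 times on the same chromosome with the same widths (100 times where Suz12 sites were split by width, 1 time for the distances to Suz12 sites); unsequenced and unmappable parts of the genome were not excluded, which lowers the random share. With 1 library per condition, the shRd and shPhf19 lists have no replicate check, and no p-value is given for any difference between them. An shRd site is called still listed when an shPhf19 site overlaps it. Differences in the share still listed, between sites with and without a factor, carry a Newcombe 95% interval. They were set against 10000 random lists of shRd sites of the same number and the same distribution over 10 width classes, as a description of these libraries. The lists were drawn from all compared sites, including those with the factor. Their mean thus carries part of any difference by the factor and does not measure the part due to width.

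Sites were named by a rule fixed before the data were examined: the 5 widest of each list, the 10 widest shRd sites still listed, the 10 widest no longer listed, and the 5 widest shPhf19 sites without an shRd site. The 13 gene lists fixed at the same time, and with them the rule to name genes, were not used here: the site lists carry no gene names, no mm9 annotation was used, and coordinates were not converted between builds. Alternatives were the definition of overlap, the sites at or above the median width of their list, autosomes alone, merged neighbouring sites, lists of equal length and other matching. The comparison by Phf19 among sites with Suz12 was also fixed beforehand. Added after the data were seen were the restriction of the changes between conditions to sites with Suz12, the comparison by Suz12 among sites without Phf19, leaving out the stretches without shRd sites, matching on 100 width classes or on Suz12 width, the split without chromosome 14, and the sites and stretches named outside the rule. The overlap counts were checked against bedtools 2.31.1, with 12 of 12 equal. The matched lists were tested on simulated data for the comparison by Phf19, over 8280 sites. With no effect beyond the width class, 93.5% of 200 simulations fell between percentiles 2.5 and 97.5. A simulated 1.5-fold effect was found in 100% of the 200. The simulated rates were constant within a class, so the simulations do not test the effect of width differences inside a class. Sites were simulated independently of each other, so the effect of neighbouring sites that stay listed together was not tested either. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.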

Results

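Phf19 is a Polycomb-like protein that binds methylated lysine 36 of histone H3 and associates with Polycomb repressive complex 2 (PRC2), the enzyme complex that methylates lysine 27 of histone H3. Suz12 is a core subunit of PRC2, and H3K27me3 is its product and a mark of silenced genes. The deposited lists held 4633 Phf19 sites, 8054 Suz12 sites, 8280 H3K27me3 sites in control (shRd) cells and 1180 H3K27me3 sites in Phf19-depleted (shPhf19) cells. Phf19 sites were narrow, with a median width of 461 bp, and covered 3.11 Mb in all. Suz12 sites had a median of 1583 bp and covered 15.5 Mb. H3K27me3 sites of the control cells had a median of 2175 bp and covered 24.3 Mb. Read depth is unknown for every list, and all lists other than that of Phf19 come from a single library.

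The first question was whether Phf19 occupies the same places as PRC2 and its mark. It did at most of its sites: 3398 of 4633 Phf19 sites, 73.3% (95% interval 72.0 to 74.6), overlapped a Suz12 site, and 72.2% (70.9 to 73.5) overlapped an H3K27me3 site of the control cells. Both a Suz12 site and a control H3K27me3 site overlapped 3199 Phf19 sites, 69.0% of the list. Random placement gave 0.846% on average for Suz12 and 1.21% for H3K27me3, and the highest of 1000 placements gave 1.25% and 1.75%. The overlap was thus 86.7-fold and 59.6-fold above chance placement.

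A second group of 1088 Phf19 sites, 23.5% of the list (22.3 to 24.7), overlapped neither Suz12 nor control H3K27me3. These sites were narrower, with a median of 374 bp against 582 bp for the sites that overlapped both. Among all 1235 Phf19 sites without Suz12, 116 had a Suz12 site within 1 kb and 18.0% had one within 10 kb, against 5.75% in a single random placement. Their median distance to the nearest Suz12 site was 82.5 kb, against 168.7 kb in that placement.

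**Figure D1:**
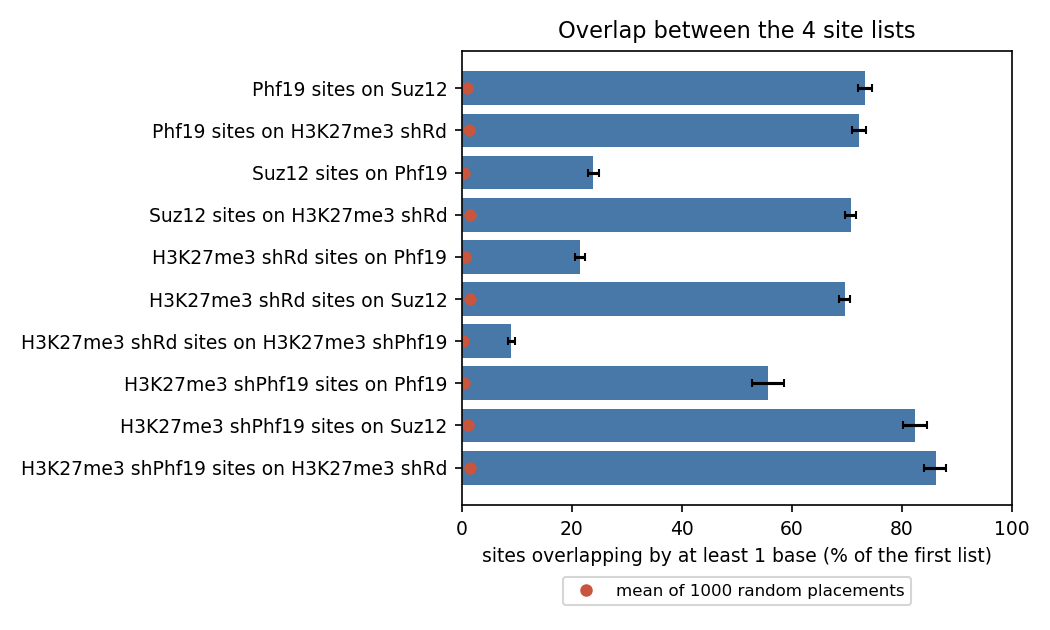
Share of the sites of one list that overlapped a site of another by at least 1 base (horizontal axis, percent; bars with exact 95% intervals) beside the mean of 1000 random placements (points). Phf19 sites lay on Suz12 sites in 73.3% of cases, whereas 23.9% of Suz12 sites carried Phf19.

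Seen from Suz12, a minority of sites overlapped a listed Phf19 site, and these were wider in the median. The Phf19 list holds only sites found in both replicates, so weaker Phf19 sites may be missing from it. Whether this lowers the share at narrow Suz12 sites was not tested. Of 8054 Suz12 sites, 1924 (23.9%, 23.0 to 24.8) overlapped a Phf19 site, and these had a median width of 2804 bp against 1357 bp for the others. Among 5 equal width classes, 4.03% of sites in the narrowest (3.13 to 5.11) carried Phf19, and in the widest 67.2% did (64.9 to 69.5). Wider sites also meet more sites by chance, but the excess over random placement grew as well, from 20.2-fold in the narrowest class to 105-fold in the widest. Control H3K27me3 was listed at 5697 Suz12 sites, 70.7% (69.7 to 71.7), which was 47.2-fold above random placement. It was listed at 1849 of the 1924 Suz12 sites with Phf19.

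**Figure D2:**
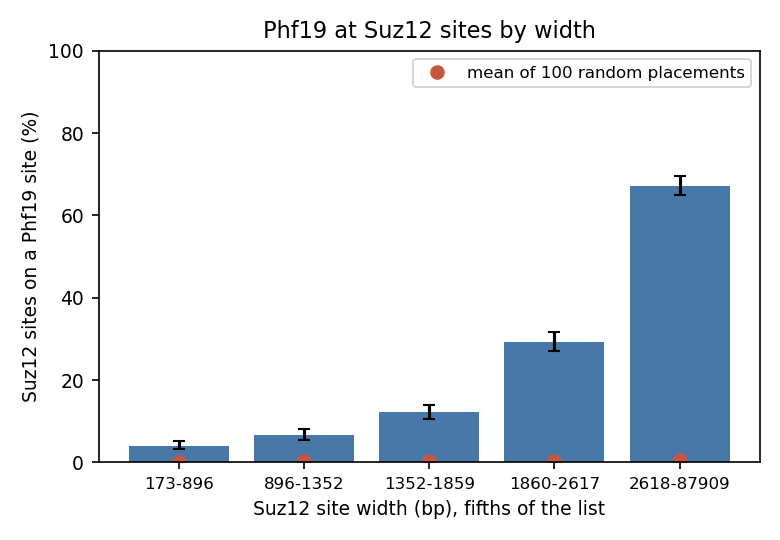
Suz12 sites that overlapped a Phf19 site (vertical axis, percent, with exact 95% intervals) in 5 equal classes of the Suz12 list by site width (horizontal axis, bp); points give the mean of 100 random placements. The share goes from 4.03% in the narrowest class to 67.2% in the widest.

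In the control cells, 5766 of 8280 H3K27me3 sites, 69.6% (68.6 to 70.6), overlapped a Suz12 site and 1776, 21.4% (20.6 to 22.3), a Phf19 site. The H3K27me3 sites with Phf19 were wider, with a median of 4092 bp against 1921 bp without. Nearly all of them, 1737 sites, also held Suz12, and 39 held Phf19 alone. Suz12 without Phf19 was found at 4029 H3K27me3 sites, and 2475 held neither. The 3 widest H3K27me3 sites with Phf19 lay at chromosome 6, 52171839 to 52210635 (38.8 kb, with 15 Phf19 sites), chromosome 11, 96180330 to 96216880 (36.6 kb, 14 Phf19 sites), and chromosome 2, 74559320 to 74595016 (35.7 kb, 9 Phf19 sites).

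A pair of the 5 widest control H3K27me3 sites had no Phf19. They lay at chromosome 6, 47686900 to 47723700, and chromosome 6, 47601285 to 47637202. Each coincided with a single Suz12 site of about the same length, 36.6 kb and 36.5 kb, and neither overlapped a site in the shPhf19 list. The widest Suz12 site, chromosome 8, 126060856 to 126148765 (87.9 kb), overlapped no site of any other list. The next in width were the 2 long Suz12 sites on chromosome 6 just given, at 47686958 to 47723560 and 47600613 to 47637156. These 3 sites lay far above the 95th percentile of Suz12 width, 4390 bp. No sequence or mappability track was used, so whether they are broad domains or artefacts of mapping was not tested. The remaining sites of the 5 widest, at chromosome 2, 33483255 to 33501442 (18.2 kb), and chromosome 11, 118895114 to 118913040 (17.9 kb), overlapped all 3 other lists. The widest Phf19 sites were at chromosome 9, 62989196 to 62997531 (8.34 kb), chromosome 19, 16945190 to 16950439 (5.25 kb), chromosome 13, 48757722 to 48762008 (4.29 kb), chromosome 3, 130811773 to 130815916 (4.14 kb), and chromosome 13, 95643745 to 95647775 (4.03 kb). All 5 overlapped Suz12 and control H3K27me3, and all but the site on chromosome 19 also overlapped an shPhf19 site.

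The second question was what depletion of Phf19 does to H3K27me3. Far fewer H3K27me3 sites were listed in the depleted cells, 1180 against 8280, a ratio of 0.143. They covered 2.07 Mb against 24.3 Mb, a ratio of 0.0853, and were narrower, with a median of 1460 bp against 2175 bp. Among sites at or above the control median width, the ratios were lower still, 0.0538 for number and 0.0409 for length. Of the control sites, 742 (8.96%, 8.35 to 9.60) still overlapped a site in the depleted cells and 7538 did not. Conversely, 1017 of the 1180 sites in depleted cells, 86.2% (84.1 to 88.1), lay on a control site. Each condition is a single library, so none of these differences has a replicate check. The labels leave open whether both libraries were made with the same antibody.

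The sites that stayed listed were wider in the median, and sites of the depleted cells covered a minor part of their length. Their median width in control cells was 5292 bp, against 2059 bp for sites no longer listed. Among 10 equal width classes of control sites, 46.1% of the widest (42.7 to 49.6) and 2.29% of the narrowest (1.39 to 3.56) stayed listed. The 742 sites still listed spanned 5176 kb in control cells, of which sites in the depleted cells covered 1705 kb, or 32.9%. Among the 1180 widest control sites, as many as the depleted list holds, 37.9% (35.1 to 40.7) were still listed.

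All 10 of the widest control sites still listed in the depleted cells held both Phf19 and Suz12. At the widest, chromosome 6, 52171839 to 52210635, 10 separate shPhf19 sites covered 24.2 kb, or 62.3% of its length. At chromosome 11, 96180330 to 96216880, 8 sites covered 35.7%, and at chromosome 2, 74559320 to 74595016, 9 sites covered 39.7%. At the others of this set, the listed part lay between 12.7% of the site at chromosome 11, 98178859 to 98203861, and 44.1% of that at chromosome 2, 33478474 to 33504191. Of the 10 widest control sites no longer listed, 4 held Phf19 and 8 held Suz12. The 4 with Phf19 were at chromosome 3, 99038256 to 99066880 (28.6 kb, 7 Phf19 sites), chromosome 19, 59524965 to 59548307 (23.3 kb, 6 Phf19 sites), chromosome 13, 83853379 to 83870282 (16.9 kb, 5 Phf19 sites), and chromosome 16, 18617946 to 18632283 (14.3 kb, 4 Phf19 sites).

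The third comparison asked whether control H3K27me3 sites with Phf19 left the list more often than the others. They stayed listed more often. Of 1776 sites with Phf19, 492 (27.7%, 25.6 to 29.8) were still listed in depleted cells, against 250 of 6504 sites without it (3.84%, 3.39 to 4.34), a difference of 23.9 percentage points (21.8 to 26.0). Random lists matched on width averaged a difference of 15.9 points, and the highest of the 10000 reached 18.5. Matched on 100 width classes the mean was 17.3 points and the highest 19.9. Such lists also include sites with Phf19, so their means do not measure the part due to width. In the widest of the 10 classes 54.8% of sites with Phf19 (50.8 to 58.8) and 21.9% of those without (16.6 to 28.0) were still listed. In the 5 narrowest classes the intervals of both groups overlapped, with 0% and 2.36% still listed in the narrowest. Where only sites with Suz12 were compared, the difference was 24.4 points (22.2 to 26.6). Lists matched on width averaged 16.6 points there, and lists matched also on the width of the Suz12 site averaged 20.2, with 22.6 the highest.

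**Figure D3:**
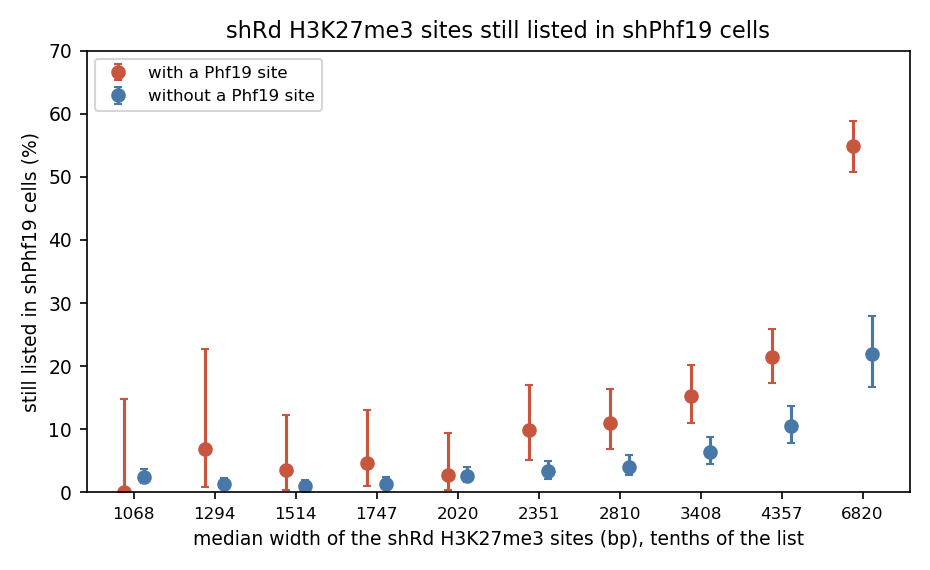
Control (shRd) H3K27me3 sites still listed in shPhf19 cells (vertical axis, percent, with exact 95% intervals) in 10 equal classes of the list by width (horizontal axis, median width in bp), with and without a Phf19 site. In the widest class 54.8% of sites with Phf19 and 21.9% of those without were still listed.

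Among sites still listed, shPhf19 sites covered a smaller share of the control length where Phf19 was present. The median was 29.7% at sites with Phf19 (interquartile range 20.8 to 39.8) and 49.6% at those without (33.8 to 82.3). The sites with Phf19 were wider in control cells, 6687 bp against 3171 bp in the median. Within the widest of the 10 classes the medians were 24.7% (16.8 to 35.1) and 26.5% (19.8 to 50.3), with overlapping interquartile ranges. There too the sites with Phf19 were wider, 8975 bp against 6694 bp, so the difference was not separated from width. The lists hold no signal, so the covered length does not measure how much of the mark was left.

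The share still listed also differed by Suz12. Control sites with Suz12 were still listed in 11.3% of cases (10.5 to 12.2) and those without in 3.58% (2.89 to 4.38), a difference of 7.73 points (6.60 to 8.80). Width-matched lists averaged 7.38 points, and the difference lay at percentile 78.6 of them, or at percentile 99.0 on autosomes alone, where it was 8.55 points. Sites with Suz12 make up 5766 of the 8280 control sites, so such lists consist mostly of them. Their mean therefore does not measure the part due to width. Among sites without Phf19, 3.97% of those with Suz12 (3.39 to 4.62) and 3.64% of those with neither factor (2.93 to 4.45) were still listed. That difference of 0.335 points (-0.652 to 1.27) lay below the mean of 1.74 points in width-matched lists, at percentile 0.09. On autosomes it was 1.09 points against 1.77 in matched lists, at percentile 4.73. Without chromosome 14, where many sites without Suz12 lie close together, the autosomal shares were 3.77% (3.19 to 4.43) and 1.57% (1.10 to 2.17). This difference of 2.20 points lay above the matched mean of 1.57, at percentile 95.7, so its side of the matched mean turned on chromosome 14. None of the 39 sites with Phf19 but no Suz12 was still listed (exact interval 0 to 9.03%).

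In the depleted cells, 55.7% of the H3K27me3 sites (52.8 to 58.5) lay on a Phf19 site of wild-type cells and 82.5% (80.2 to 84.6) on a Suz12 site. The 5 widest all lay on control sites. Those at chromosome 14, 4178444 to 4190999 (12.6 kb), chromosome 14, 3121995 to 3131653 (9.66 kb), and chromosome X, 166409468 to 166418538 (9.07 kb), overlapped neither Phf19 nor Suz12. That at chromosome 14, 5727206 to 5736736 (9.53 kb), overlapped Suz12 without Phf19, and that at chromosome 5, 26332052 to 26340590 (8.54 kb), overlapped both. There were 163 sites in the depleted cells without a control site. Of these, 93 held no Suz12, part of them in a few windows given under the other observations. The other 70 lay on Suz12 sites, 57 of them in 7 stretches between neighbouring control sites. These stretches were chosen after their sites were seen. The stretch with the largest number of shPhf19 sites was at chromosome 15, 102785658 to 102854351, where 68.7 kb without a control H3K27me3 site held 20 shPhf19 sites, 23 Suz12 sites and 33 Phf19 sites. Similar stretches at chromosome 11, 96126761 to 96180330 (53.6 kb), chromosome 2, 74511251 to 74559320 (48.1 kb), and chromosome 6, 52141804 to 52171839 (30.0 kb) held 10, 10 and 7 shPhf19 sites. These last 3 border the 3 widest control sites with Phf19 given above. The stretches on chromosomes 1, 16 and 4 held 5, 3 and 3 shPhf19 sites and 1, 7 and 0 Phf19 sites. Suz12 sites covered 8.36%, 26.2% and 19.3% of their length, against at least 66.3% of the stretches on chromosomes 15, 11, 2 and 6. The 5 widest sites without a control site were at chromosome 16, 35537030 to 35545312 (8.28 kb), chromosome 1, 173005339 to 173012865 (7.53 kb), chromosome 17, 39979470 to 39986185 (6.72 kb), chromosome 11, 96133158 to 96139784 (6.63 kb), and chromosome Y, 1262960 to 1268657 (5.70 kb). Those on chromosomes 16 and 11 held Phf19 and Suz12, that on chromosome 1 Suz12 alone, and those on chromosomes 17 and Y neither.

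**Figure D4:**
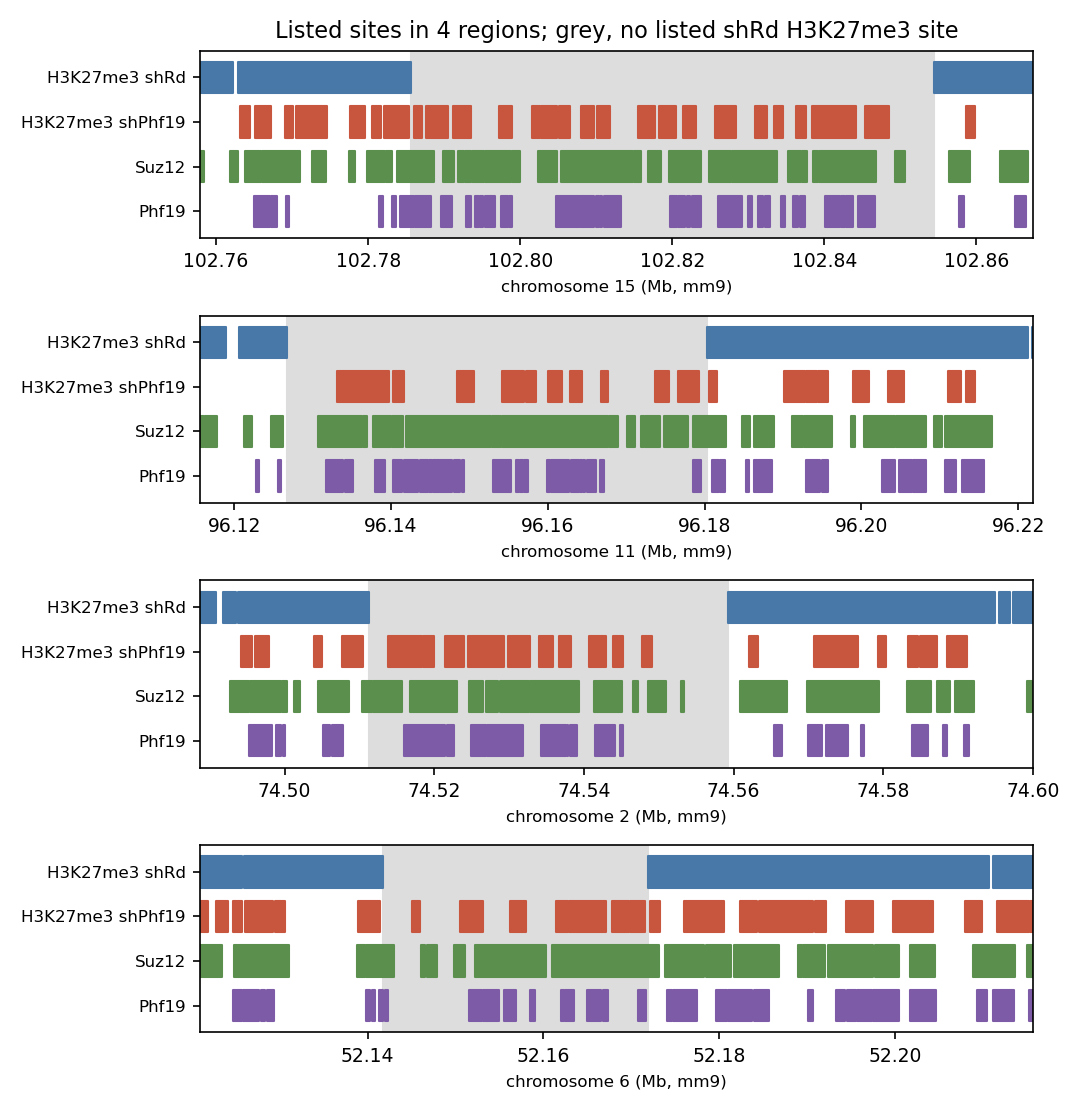
Sites of the 4 lists (rows) along 4 regions of mm9 (horizontal axis, Mb); grey marks the stretch between 2 neighbouring control (shRd) H3K27me3 sites. The 4 stretches, chosen after the data were seen, hold 20, 10, 10 and 7 shPhf19 H3K27me3 sites and no control site.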

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

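The restrictions to sites with Suz12 (other than for the difference by Phf19) or without Phf19, the removal of the stretches and the 100 width classes were chosen after seeing the data. Of 73 alternatives, 4 changed only the random lists and so could not move the value. Of the others, 35 stayed within the interval of the reported value, or within 1.5 times it for the 2 ratios between conditions, and 34 moved beyond that. Shares and ratios cannot change sign, and 0 of the 14 alternative differences did. The interval of the difference by Suz12 among sites without Phf19 held 0, however (-0.652 to 1.27). The difference by Phf19 stayed between 18.0 and 24.9 points and above all random lists under its 8 alternatives, lowest among sites at or above their list's median width (18.0). With at least 50% of the shorter site shared, Phf19 sites lay on Suz12 in 71.7% and on control H3K27me3 in 70.5% of cases, Suz12 sites on control H3K27me3 in 63.7%, control H3K27me3 sites on Suz12 in 56.1%, and the difference by Suz12 was 10.2 points. Counting sites within 1 kb gave 75.8%, 74.0%, 72.4% and 73.3% for those 4 shares, 26.9% for Suz12 on Phf19 and 10.3% for control sites still listed. Among sites at or above their list's median width the 4 shares were 88.5%, 85.3%, 74.0% and 70.7%, Suz12 on Phf19 was 32.1%, and depleted on control sites 81.7%. Merging neighbours within 1 kb gave 61.7%, 61.4%, 69.7% and 71.7%, and 10.3% still listed. On autosomes Suz12 lay on control H3K27me3 in 72.2% and depleted on control sites in 88.8%. At widths of the control median or above, the ratio of site numbers was 0.0538 and that of covered length 0.0409. The share still listed was 37.9% for the 1180 widest control sites. Restricting both H3K27me3 lists to sites on Suz12, with or without Phf19, gave 11.2% still listed and 92.8% of depleted on control sites, and leaving out the stretches gave 90.3% for the latter. The difference by Suz12 was 0.335 points among sites without Phf19 (percentile 0.09 of matched lists) and 1.09 points on autosomes (percentile 4.73), and 2.20 points on autosomes without chromosome 14 (percentile 95.7). Its percentile ranged from 0.09 to 99.4 over the width-matched alternatives, so whether Suz12 adds to width depends on them. For these moved values the cause was not tested. No paired analysis was possible because the compared lists carry no replicate numbers. Leaving out a Phf19 replicate, and the alternatives for the gene lists, were not run, since 1 Phf19 list of sites common to both replicates was used and genes were not named. Sites just under a peak threshold are not listed, and without read depth a missing site does not show a missing mark.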

Other observations

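The tests below on the peak threshold and on the stretches were chosen after the result was seen. Matching on 10 width classes was planned, but what it would show of width was written down after its result was seen; the tests with 100 classes, with Suz12 width, of positions in domains and of the X were added after the data were seen, before their own results. Suz12 sites on the X chromosome overlapped the other lists less often than those on autosomes. Phf19 sites numbered 0.216 per Mb on the X and 1.86 per Mb on autosomes, control H3K27me3 sites 0.744 and 3.30, Suz12 sites 1.46 and 3.16, and H3K27me3 sites of the depleted cells 0.258 and 0.453. The Y had 0.0629, 0.566, 0.314 and 1.01 per Mb in the same order, from 1, 9, 5 and 16 sites. Of 244 Suz12 sites on the X, 24.6% (exact 95% interval 19.3 to 30.5) overlapped control H3K27me3, against 72.2% (71.2 to 73.2) on autosomes, and 9.43% (6.07 to 13.8) overlapped Phf19, against 24.4% (23.4 to 25.3). Suz12 sites on the X were narrower, 1223 bp against 1595 bp in the median, but autosomal Suz12 sites of matched widths overlapped H3K27me3 in 62.2% of cases on average, and the lowest of 10000 such lists gave 51.6%, so width alone does not account for the difference. No other explanation, technical or biological, was tested for it. Copy number of the X, read depth and mappability were not examined.

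In the depleted cells, H3K27me3 sites without Suz12 were concentrated in a few windows. Of 207 such sites, 31 lay between 120 and 125 Mb of the X, 29 in the first 5 Mb of chromosome 14, 25 between 5 and 10 Mb of chromosome 14, and 15 in the first 5 Mb of the Y. In these windows, 13, 19, 15 and 3 of the sites, in that order, lay on a control site. The remainder are among the 93 sites with neither Suz12 nor a control site. The control list held 39, 23 and 26 sites without Suz12 in the first 3 of these windows, of 2514 in all. The widest site of the depleted cells, chromosome 14, 4178444 to 4190999 (12.6 kb), lies in one of them. No sequence or mappability track was used here.

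The first pattern is that control H3K27me3 sites with Phf19 stayed listed more often, by 23.9 percentage points. Width of the site does not explain all of it: the difference lay at percentile 100 of lists matched on 10 and on 100 width classes. The same held among sites with Suz12 when the width of the Suz12 site was matched as well (percentile 100). There the difference was 24.4 points and the matched lists averaged 20.2. The matched lists also include sites with Phf19, so how much of the difference is due to width cannot be read from their mean. A lower yield or a stricter effective threshold in the shPhf19 library may leave mainly the strongest domains listed, with or without an effect of depletion. The lists hold no heights, and the labels leave open whether the antibody was the same, so this cannot be told apart from a change of the mark.

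The second pattern is the 7 stretches in which the depleted cells, but not the control cells, had 3 or more H3K27me3 sites on Suz12. An upper limit on site width in the control list could remove the broadest domains, but that 6 stretches are longer than the widest listed control site of 38.8 kb decides nothing, since a gap between sites is not the width of a domain. For the remaining 1 stretch, on chromosome 6, a limit of that kind is argued against, because its 30.0 kb is shorter than a listed site. H3K27me3 present only after depletion cannot be told apart from a gap in the control list without the control reads: 51 of the 72 Suz12 sites in the stretches carried an shPhf19 site, but the stretches were chosen for such sites, so the number has no bearing on it.

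The third pattern concerns where shPhf19 sites lay inside control domains. A hypothesis is that H3K27me3 remains at the places that Phf19 occupies in wild-type cells. Of 746 shPhf19 sites lying wholly inside 480 control domains with Phf19, 79.9% (76.8 to 82.7) overlapped a Phf19 site. Random positions in the same domains gave 64.6% on average and at most 70.8% in 1000 draws, and the mirrored position, which keeps the distance from the edge of the domain, gave 62.7% (59.2 to 66.2), so domain width and edge distance do not account for it. The same comparison for Suz12 gave 97.2% (95.9 to 98.2) against 88.0% (85.6 to 90.0) at mirrored positions, so the placement may follow PRC2 in general, or the places of highest signal, which the lists do not give.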
